A study of Mus musculus with 18 samples.

How the data were processed

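Genomic DNA from the tails of 9 C57BL/6 mice, 1 sire, 1 dam and 7 offspring, was compared with DNA of 1 reference male by array comparative genomic hybridisation, in which 2 DNA samples carrying different dyes compete for the probes of 1 array. The labels name the dye of each channel. Each mouse has 1 array with its DNA in Cy5 and 1 with its DNA in Cy3, and these 2 arrays of the same DNA were treated as 1 replicate. Groups and dyes were taken from the labels.

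Per the file headers, the arrays were Agilent 2-colour arrays with positions on mouse build mm9, extracted with Feature Extraction 12.1.0.3. Each file holds 973116 spots, of which 6745 are controls. The deposited intensity values are the processed signals of both dyes, background-subtracted and linearly dye-normalised by that software, per the file headers, and the raw median spot and background intensities. The deposited log10 ratio of Cy5 over Cy3 was used only to find the direction of the value table. The authors' value table for the series holds log2 ratios, and how it was made is not given in the sources used here. Set against the scanner values, each of its 18 columns followed the log2 ratio of reference over mouse, with r from -0.999 to -0.974 and slopes from -0.999 to -0.948 against mouse over reference. Its sign was therefore turned. Column medians lay between -0.006 and 0.014, and its further normalisation stays unknown.

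From the processed signals the log2 ratio of mouse over reference was computed for each spot. Control spots, spots marked as non-uniform or population outliers (133 to 2267 per array) and probes outside the autosomes, X and Y were left out. Repeated spots of a probe (15622) were averaged, and each array was centred on its autosomal median. No loess or quantile normalisation was applied, because most probes carry signal. Between 112 and 3239 probes per array were not well above background in at least 1 channel, and none was saturated. Arrays of different mice in the same dye orientation correlated with r from 0.143 to 0.566 over autosomal probes, while the 2 orientations of a mouse correlated with r from -0.402 to 0.0002, so a dye effect recurs at the same probes. It was estimated as the median over mice of the halved difference of orientations (SD 0.132 over probes) and cancels in the mean of the orientations.

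Regions were called by a recursive interval scan along each of 19 autosomes on the mean of both orientations. The interval score was the summed log2 ratio divided by the noise SD and by the square root of the number of probes. A call needed a score of 6 or more, 3 to 2000 probes, an absolute mean of 0.25 or more, and 0.15 or more in each orientation in the same direction. Overlapping calls were merged with the boundaries of the highest score, and a mouse carried a region when it met the same 2 limits on the mean. The same scan of the halved difference of orientations counted what noise that differs between the 2 arrays of a mouse gives. Any effect that both arrays share cancels there along with copy number, so these noise tracks leave it out. After the data were seen, a region was called well supported when it held 5 probes or more and scored above every such interval in the 9 noise tracks with the dye effect removed (12.6). The same rule was applied to the tracks of offspring minus mid-parent (10.68) and sire minus dam (7.39). A permutation p for each region and mouse came from 10000 random autosomal windows with the same number of probes, two-sided, and 1e-04 is the smallest it can give. With the dye effect removed the noise tracks had SDs of 0.0788 to 0.106 between neighbouring probes, against 0.0919 to 0.162 in the real tracks, so they are a guide and not a full model of noise. Each track was scored by its own noise SD. Counts and scores of real and noise tracks therefore do not rest on the same limit in log2.

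Offspring and parents were compared per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on 1 value per mouse, Benjamini-Hochberg at 0.05). Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and statsmodels 0.14.6, with figures from matplotlib 3.10.9. The scan was tested on simulated gains added to the noise tracks of the 9 mice with the dye effect removed, with 950622 probes. It found 224 of 225 added 3-probe gains of 3 copies over 2. Of gains of 5 over 4 it found 107 of 225 with 3 probes and 207 of 225 with 5 probes. These tracks had lower noise SDs than the real ones in every mouse but offspring 7, and the gains were added at full size. The shares may therefore be too high for the real tracks. Without added gains these tracks gave 1340 calls. Tested on simulated data with 946400 probes, the limma comparison found 49 of 100 probes raised from 2 copies to 3 in every offspring and 91 of 100 raised from 1 to 2, with 3 false calls. The number of arrays limits the precision.

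Tests, alternatives and the rule for named items were fixed before the data were examined. The alternatives were other scores, probe numbers and means, normexp background correction (offset 50), the authors' value table, subtraction of a running median over neighbouring probes, removal of dim probes, each dye orientation alone, merging at an overlap of 0.5 of the shorter call, leaving out each mouse, and scan day as a random block. Mean spot signals were not used here, so normexp ran on the median spot and background signals. The rule was to name genes of the regions with the highest scores and to give each offspring-only region by position. No gene names were used here: the files give positions on mm9 alone and the gene table at hand is on another build. The gene-level comparison and the gene lists were therefore not run, and regions are given by position. Of the 639 offspring-only regions, too many to print, a few were named. Those scoring below the noise were picked after their values were seen. Score and agreement of the orientations were weighed, but the picks follow neither strictly.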

Results

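Tail DNA of 1 mouse family was hybridised on whole-genome tiling arrays to look for DNA copy number changes that pass from parents to offspring or arise anew in the offspring. The family was 1 sire, 1 dam and 7 offspring of the inbred strain C57BL/6. The series belongs to a study of males kept under continuous gamma-rays at 0.05 mGy per day for 400 days. Its title counts this family among the exposed ones, while its design text calls the sire of this family non-irradiated, so its exposure is left open here and no comparison below rests on it. Each mouse was hybridised on 2 arrays, with the dyes swapped, against DNA of 1 reference male from the same colony. The 18 arrays gave 9 mice with 1 value each, and no mouse has a biological replicate. A log2 ratio of 0 means as many copies as in the reference male. A copy number change that this male alone has therefore appears in all 9 mice with the sign turned. One that a mouse shares with him cancels in that mouse. The arrays held 950622 distinct autosomal probes with a median spacing of 2053 bases (mm9). The median signal lay 4.89 to 10.22 times above background, and the SD of neighbouring probes in the dye-swap mean lay between 0.0919 in offspring 2 and 0.162 in offspring 3.

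The first question was which autosomal regions differed from the reference male in each mouse. Of the regions of 5 probes or more, 5 scored above all noise intervals of that size, on chromosomes 4, 8, 10, 13 and 14. They held 16 to 74 probes each and scored between 17.99 and 48.61, against 12.6 for the highest of those noise intervals. On chromosome 4, the dam, offspring 1 and offspring 6 had a gain over 160 kb (mm9 101110482 to 101270535, 74 probes), with a mean log2 ratio of 0.54 ± 0.003 (SD, n = 3 mice). The other 6 mice averaged -0.005 there. The gain was a copy ratio of 1.46, where 3 copies against 2 would give a log2 ratio of 0.58. On chromosome 10, 8 of the 9 mice lay below the reference over 36.2 kb (33897213 to 33933441, 19 probes), with a mean of -0.57 ± 0.03 (SD, n = 8 mice), or a copy ratio of 0.673. Offspring 7 lay at 0.02. The mean of the 8 mice lies near the -0.58 that 2 copies against 3 in the reference male would give. It need therefore not be a loss in the family. On chromosome 13, the dam and offspring 1, 2 and 6 had a loss over 49.97 kb (101027565 to 101077537, 16 probes), with a mean of -0.40 ± 0.02 (SD, n = 4 mice), against -0.03 in the other 5 mice. On chromosome 14, the mean of each of the 9 mice lay below the reference over 570.2 kb (53424661 to 53994906, 63 probes), at -0.35 ± 0.10 (SD, n = 9 mice). The value of offspring 7, -0.57, was lower than the -0.44 to -0.28 of the other 8. On chromosome 8, the dam and offspring 3 to 7 lay between 0.20 and 0.25 over 124 kb (102129465 to 102253497, 44 probes), while the sire lay at 0.05, offspring 1 at 0.01 and offspring 2 at 0.00. Of these, offspring 4 alone reached the 0.25 set for a carrier. In a permutation test against 10000 random autosomal windows, 3890 of 10611 tests passed (two-sided, Benjamini-Hochberg). As the regions had been chosen for their means, this test does not tell them apart from noise.

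**Figure D1:**
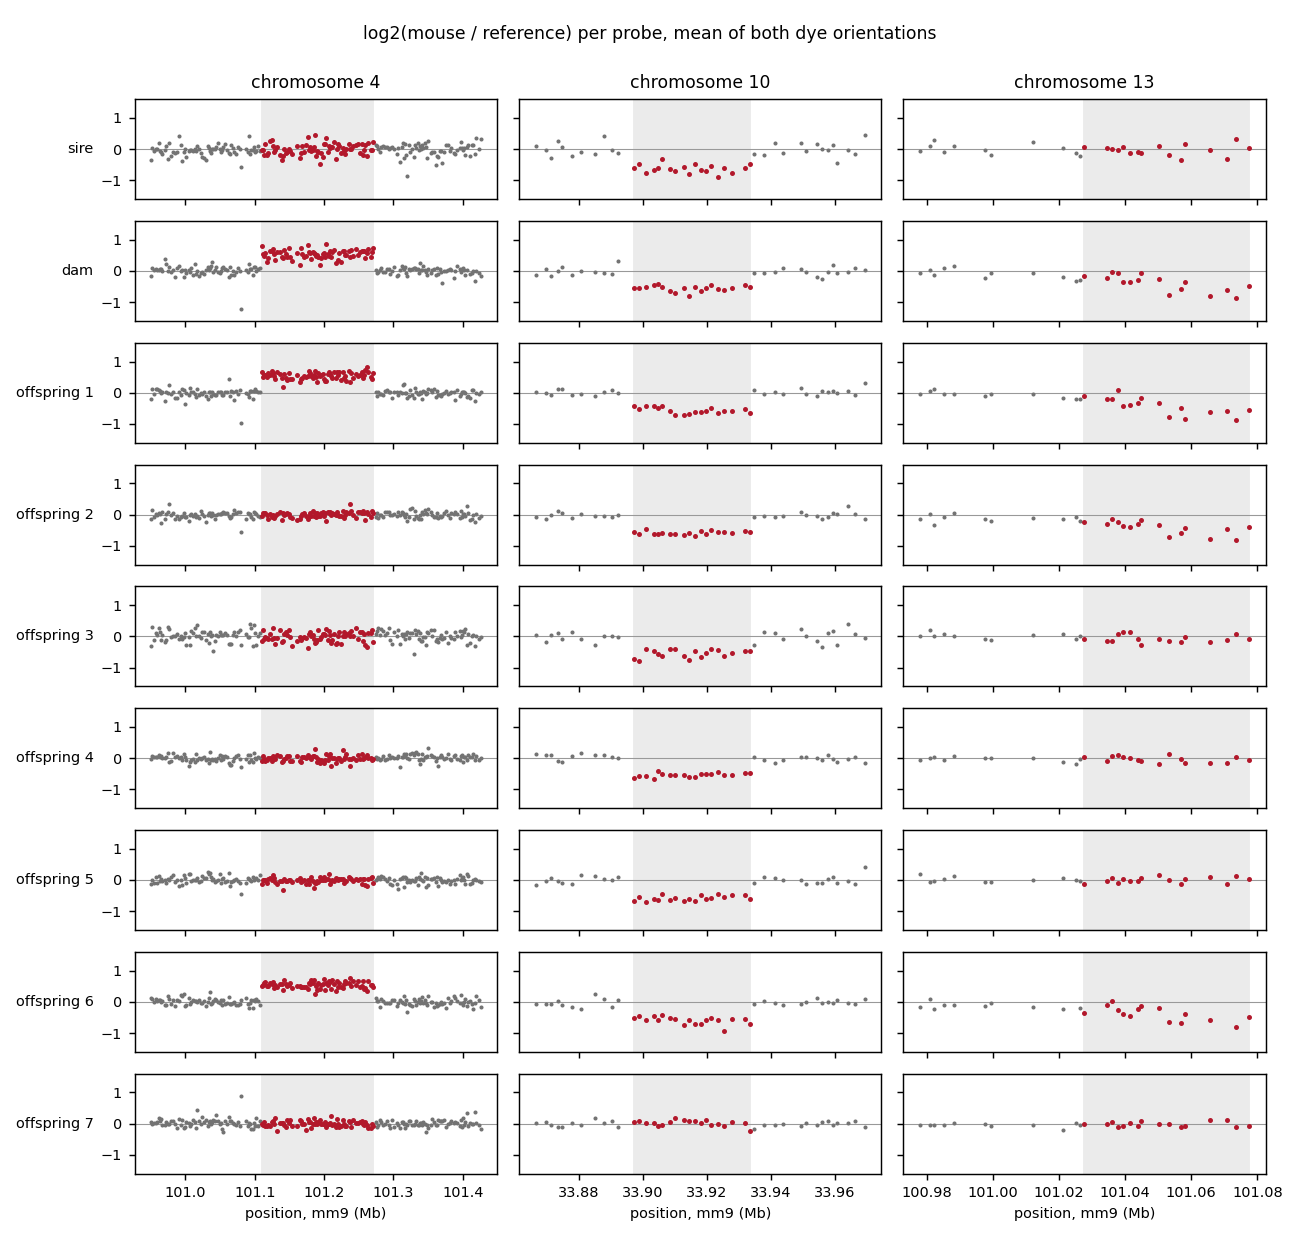
Log2 ratio of mouse over reference (vertical axis) of each probe against its position in Mb on mm9 (horizontal axis), for 9 mice in rows and the regions on chromosomes 4, 10 and 13 in columns. Red points are probes inside the region (shaded) and grey points are probes beside it. The dam, offspring 1 and offspring 6 share the gain on chromosome 4. On chromosome 10 offspring 7 lies near the reference, while the other 8 mice lie below it.

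**Figure D2:**
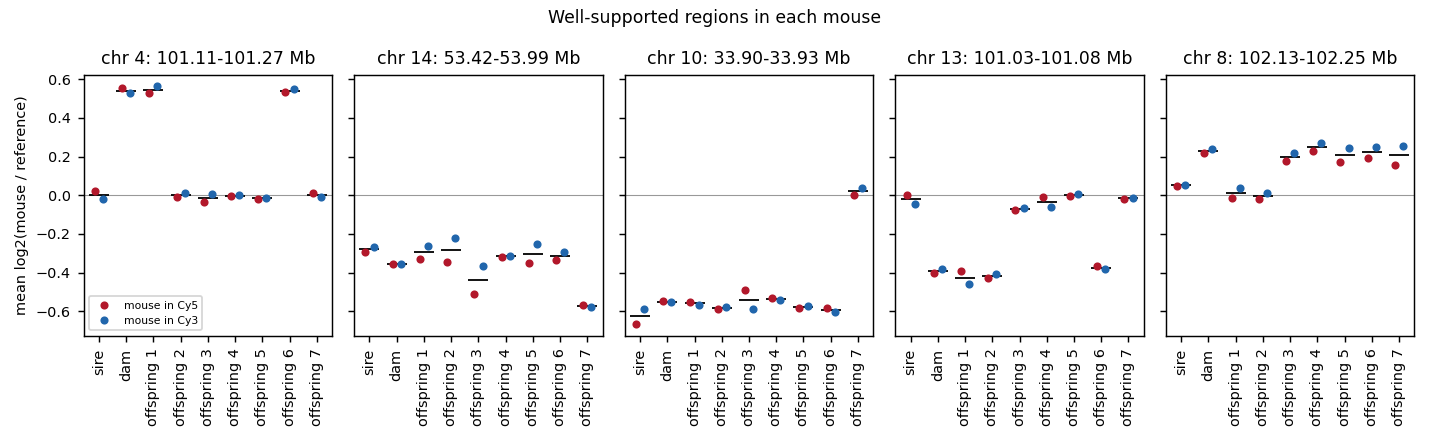
Mean log2 ratio of mouse over reference (vertical axis) in each mouse (horizontal axis) for the 5 well-supported regions. Red points are the array with the mouse in Cy5, blue points the array with the mouse in Cy3, and black bars their mean. The 2 orientations lie close together, and offspring 7 stands apart on chromosome 10 at 0.02.

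Apart from these regions the scan called many short intervals, at numbers that depended on the noise track and the processing. Over the 9 mice it called 1537 regions (693 gains and 844 losses), from 37 in offspring 3 to 338 in offspring 7, and 1184 of them held 3 probes. In 858 of them the median over the probes stayed under 0.25 while the mean passed it. In the halved difference between the orientations, where copy number and any other effect shared by both arrays cancel, the same scan called 346 regions. With the recurring dye effect of each probe removed, it called 2077 regions in the mice and 1340 in the noise tracks. On this footing the noise count stood above the real one in offspring 1 (298 against 276), offspring 4 (200 against 104) and offspring 6 (214 against 156). It stood below in the other 6 mice, among them the dam (87 against 230), offspring 2 (63 against 289) and offspring 7 (83 against 465). Each track was scored by its own noise SD, so these counts do not rest on the same limit in log2. In offspring 4 this SD was 0.0922 in the real track. Its noise track had 0.143 with the dye effect kept and 0.0788 with it removed. With normexp background correction and the dye effect kept, the scan called 585 regions in the mice and 43 in the noise tracks (71 in noise tracks with the dye effect removed). How many of the 1537 are copy number changes stays open. Of the 1030 merged regions under 5 probes, 20 scored above 12.6, and 3 scored above 17.33, the highest score of a noise interval of 3 or 4 probes. These 3 lay on chromosome 1 (178985506 to 178991600, 3 probes), chromosome 3 (25417435 to 25432738, 3 probes) and chromosome 11 (20162959 to 20174473, 3 probes). On chromosome 1 the mice were spread from -1.18 in offspring 5 to 1.19 in offspring 2.

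**Figure D3:**
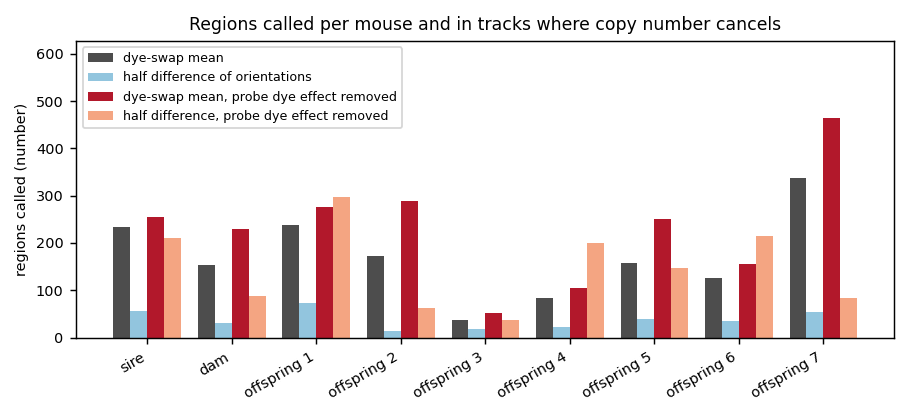
Number of autosomal regions called (vertical axis) in each mouse (horizontal axis). Dark bars are calls in the dye-swap mean and blue bars calls in the track where copy number cancels. Red and orange bars are the same 2 tracks after the dye effect of each probe was removed. Offspring 7 had 465 calls against 83 in red and orange, whereas offspring 4 had 104 against 200.

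The family was then used to ask which regions were shared by a parent and its offspring. The chromosome 4 gain was in the dam and 2 of 7 offspring, and the chromosome 13 loss in the dam and 3 of 7. Neither share could be distinguished from an even chance of transmission (exact binomial test, two-sided, p = 0.453 and p = 1). Of these 2 regions, which the sire did not carry, offspring 1 and offspring 6 had both and offspring 2 had the one on chromosome 13. Offspring 3, 4, 5 and 7 had neither. No well-supported region was carried by the sire and not by the dam. Merging overlapping calls of all mice gave 1179 regions. Of these, 318 were carried by a parent and an offspring, 220 by 1 or both parents and no offspring, and 639 by offspring alone. The region on chromosome 14 was carried by all 9 mice. 1 further region was carried by no mouse under the rule for carriers. Of the 220, 95 held 5 probes or more, against 8 of the 318 and 45 of the 639. The sire had 99 calls of that size and the dam 10.

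Offspring-only regions are what a new mutation in the germ line would give. Of the 639, 505 held 3 probes, 465 were carried by a single offspring, and the chromosome 8 region, at 0.23 in the dam, was the 1 of 5 probes or more that scored above the noise. Of the shorter ones, 11 scored above 12.6 and 1 above 17.33, the chromosome 11 region at 20162959. There offspring 1 lay at 1.29, offspring 6 at 0.77, the sire at 0.63 and offspring 4 at 0.58, and the other mice between -0.17 and 0.20. Among the short ones, the following were picked after their values were seen. Offspring 7 had a loss of -0.65 on chromosome 3 (71231170 to 71245229, 4 probes), with -0.64 and -0.66 in the 2 orientations, while the other 8 mice lay between -0.26 and 0.11. Offspring 5 had a loss of -0.53 on chromosome 10 (79757455 to 79763004, 4 probes), with -0.46 and -0.61 in the 2 orientations and -0.16 to 0.08 in the other mice. Elsewhere the orientations lay far apart, as on chromosome 14 in offspring 6 (113661688 to 113666211, 3 probes), with 1.26 with the mouse in Cy5 and 0.23 with the mouse in Cy3. On chromosome 15 in offspring 5 (86027996 to 86031751, 3 probes) they were -1.27 and -0.23. None of these regions has a replicate, and their scores of 10.06 to 13.45 lie below the 17.33 that a noise interval of 3 or 4 probes reached. A region on chromosome 11 (76357341 to 76361590, 3 probes) scored higher, at 15.16, and was not among these picks. There offspring 2 lay at 0.80, with 0.93 and 0.68 in the 2 orientations, and the sire at 0.79.

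Each offspring was also set against the mean of its parents, which removes the reference male from the comparison. On chromosome 10, offspring 7 stood above the mid-parent value by 0.63 in log2 (33897213 to 33932082, 18 probes), with 0.62 and 0.63 in the 2 orientations. Over the whole region its siblings averaged -0.57 ± 0.02 (SD, n = 6), and offspring 7 was the highest of all 9 mice at each of the 19 probes. On chromosome 14 it differed from the mid-parent value by -0.27 (53415714 to 53987490, 61 probes). All 7 offspring differed from the mid-parent value at the chromosome 4 region, by 0.28 in offspring 1 and 6 and by -0.29 to -0.27 in the other 5. With the dam at 0.54 and the sire at 0.00, any offspring with or without the gain differs from the mid-parent value by that much, so these 7 differences follow from the dam's gain. They and the 2 of offspring 7 were the 9 differences of 5 probes or more above the noise. The scan called 1358 regions over the 7 offspring in all, from 56 in offspring 4 to 635 in offspring 7, against 479 in the noise tracks. Offspring 7 (635 against 49), offspring 5 (285 against 89) and offspring 3 (159 against 24) held the excess. Offspring 4 had 56 against 51, and the noise count was the higher in offspring 1 (87 against 111), offspring 2 (65 against 70) and offspring 6 (71 against 85). With normexp background correction the totals were 568 against 16.

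Sire and dam were compared directly. The highest score was that of the chromosome 4 gain of the dam, at -0.54 for sire minus dam. Larger differences lay over 5 probes each on chromosome 14, at 0.86 (53961688 to 53987490, 0.53 and 1.18 in the 2 orientations) and at 0.81 (64762911 to 64768603, 1.41 and 0.21). The first of these stretches lies inside the chromosome 14 region in which the mean of every mouse was low, and there the sire stood above the reference at 0.33 and the dam below it at -0.53. On chromosome 13 the sire stood 0.56 above the dam in the second part of that region (101050371 to 101077537, 8 probes), where the dam lay at -0.59 and offspring 1, 2 and 6 at -0.63, -0.56 and -0.54. A further 13 of the 19 differences of 5 probes or more above the noise were stretches of 10 probes or more in which the sire lay low, by -0.36 to -0.25. The sire was at -0.31 to -0.16 against the reference there, while the offspring stayed between -0.10 and 0.12. These 13 scored 7.41 to 10.26, and the limit of 7.39 came from the sire minus dam noise track alone. Against the reference, the sire had 61 regions of 10 probes or more. After the running median was subtracted it had 10, and with the authors' values 10. Whether the 13 are the same stretches was not tested. The scan of sire minus dam called 260 regions in all, against 142 in the noise track. The counts were 170 against 134 after the running median was subtracted, 176 against 132 with the authors' values, and 115 against 7 with normexp background correction.

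The comparison with more than 1 mouse on each side was that of 7 offspring with 2 parents. No autosomal probe of the 946400 tested differed after adjustment (limma, smallest adjusted p = 0.147). At an unadjusted p under 0.05 there were 97842, or 10.3% of the probes, where chance would give 5%. The smallest p values were those of a probe on chromosome 8 (16372087 to 16372146), with an offspring mean of -0.06 and a parent mean of 0.53, and a probe on chromosome 3 (66925710 to 66925769), with -0.13 and 0.49. In the other direction, a probe on chromosome 2 (130900425 to 130900470) had an offspring mean of -0.05 and a parent mean of -0.48 (limma, adjusted p = 0.147 for all 3 probes). Both parents were scanned on 1 day and no offspring on that day, so generation and scan day cannot be told apart. With scan day as a random block the count was also 0, but a block cannot separate the day of the parents from their generation. Leaving out the dam gave 732 probes and leaving out the sire 32, with 1 parent left and its spread assumed equal to that of the offspring.

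Single probes were counted because the study screened probes by aberration under both dyes. Over the 9 mice, 230 probes had a log2 ratio of 1 or more in size in both orientations and the same direction, and 156 had it in opposite directions, which copy number cannot give. The sire had 72 such probes in the same direction and 42 in opposite ones, and offspring 7 had 41 and 15, of which 30 of the 41 were higher in the mouse. Opposite directions were the more frequent in offspring 1 (37 against 24), offspring 2 (10 against 5) and offspring 5 (24 against 21). At 0.5 the counts were 9495 and 14661, so that opposite directions prevailed. With normexp background correction, 70 probes passed 1 in the same direction and 2 in opposite ones.

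The X chromosome served as a known difference, 2 copies in a female against 1 in the reference male. The median over 68 X probes was 0.94 in the dam (0.91 with the mouse in Cy5 and 0.94 in Cy3), a copy ratio of 1.92, and -0.01 in the sire. The 23 Y probes had a median of -2.30 in the dam and 0.06 in the sire. With normexp background correction the X median of the dam was 0.785.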

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

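The tests of explanations in this part (array fault, label, copy number, wave and inheritance) were chosen after the results were seen. Among 11 sets of values over the 7 offspring, 4 held 1 mouse far from the others, where chance gives about 1 set in 20. These sets overlap, since 2 of the 4 concern offspring 3 and 2 concern offspring 7.

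Offspring 7 lay at 0.0198 in log2 on chromosome 10 (33897213 to 33933441), while the nearest sibling lay at -0.54 and the lowest at -0.59. A fault of 1 array is argued against, since the 2 orientations differed by 0.0385, where a fault would have needed 0.3 or more. The difference from the mid-parent value of 0.61 lies near the 0.58 that 3 copies against 2 would give, so 1 copy more than in the parents is a candidate explanation. At 0.0198, offspring 7 lay at the level of the reference male, who is from the same colony. The values therefore cannot show that such a copy is new. DNA of another mouse under this label could also give this difference. Of the other 4 well-supported regions, offspring 7 lay outside both parents by 0.15 or more at 1, on chromosome 14, and its siblings at 0. On chromosomes 4, 8 and 13 the sire lay at 0.00, 0.05 and -0.02. Another mouse at the reference level would not lie outside both parents there by that much, so this count cannot decide. Both explanations stay open, a new copy number change among them, and offspring 7 was also the one mouse of its scan day.

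The sire had 61 regions of 10 probes or more, 57 of them losses, while the other 8 mice had 3 to 6 each. Subtracting the running median left 10, which a slow wave along the chromosomes would give. Normexp background correction left 9, the authors' values left 10, and a mean of 0.4 left 3, so this fall does not single out a wave. The scan of 1 orientation gave the sire 6 with the mouse in Cy5 and 124 with the mouse in Cy3. Germline variants of the sire are argued against, because 2 of the 61 were carried by any offspring, where inheritance would have given nearly all of them. The medians over these regions were -0.27 in the sire (-0.21 with the mouse in Cy5 and -0.33 in Cy3) and -0.07 to 0.04 in the offspring. What stays open is their source, a wave in 1 or both of the sire's arrays among them. A call in the mean of both orientations needed 0.15 in each, so the 61 cannot show whether 1 array gave them. The scans of 1 orientation carry no such limit on the other array, and there the long regions lay mostly in the Cy3 array.

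The X and Y probes of the offspring lie outside the comparisons of the report, and the X probes were used only to divide the offspring under the other observations. The X median was 0.91 in offspring 3, 0.92 in offspring 4, 0.97 in offspring 5, 0.97 in offspring 6 and 0.96 in offspring 7, each far above the -0.01 of the sire, and 0.01 in offspring 1 and 0.00 in offspring 2. On the Y probes offspring 1 and 2 lay at 0.01 and 0.00, and offspring 3 to 7 at -3.13, -2.26, -2.77, -2.14 and -2.92, against -2.30 in the dam and 0.06 in the sire. The labels give no sex for the offspring.

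Offspring 7 had 274 gains among its calls, against 98 in the next offspring and 8 in the lowest. Offspring 3 had the highest noise SD, 0.162 against 0.112 in the next offspring. Its 2 orientations correlated with r = 0.0002, where the next offspring had -0.285 and the lowest -0.402.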

How the results depend on the processing

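The 5 well-supported regions were called again in at least 1 mouse under each setting that was run, except that a mean of 0.4 gave 4 of the 5. With 16 probes or more and scores of 17.99 or more, they had to pass the other limits on score and probe number. Over all settings the gain on chromosome 4 kept a value of 0.51 to 0.55 in offspring 6. In offspring 2 the chromosome 10 region kept -0.65 to -0.56 and the loss on chromosome 13 -0.43 to -0.36. The chromosome 14 region kept -0.60 to -0.52 in offspring 7. Settings that change only thresholds, merging or the dye effect leave these values as they are by construction. The ranges therefore come from the settings that change the log2 ratios. The chromosome 8 region ran from 0.22 to 0.27 in offspring 4, under the limit of 0.25 for a carrier with the running median subtracted (0.2173), the mouse in Cy5 only (0.23) and dim probes left out (0.2499), so whether offspring 4 carries it depends on the setting. The totals of short calls moved with the thresholds, and the cause was not tested beyond the thresholds themselves. A score of 5 gave 4104 calls, 588 regions of parent and offspring, 765 of parents only, 1798 of offspring only, 3937 offspring minus mid-parent and 782 sire minus dam. A score of 8 gave 349, 92, 22, 131, 267 and 47 in the same order. Requiring 5 probes gave 631 calls, 60 regions of parent and offspring, 284 of offspring only and 643 offspring minus mid-parent. A mean of 0.4 gave 964 calls, 0 regions in all 9 mice, 102 of parent and offspring and 402 of offspring only. With normexp background correction there were 585 calls, 98 regions of parent and offspring, 117 of offspring only, 568 offspring minus mid-parent and 115 sire minus dam, 70 single probes and an X median of 0.785 in the dam. The authors' value table gave 143 regions of parents only. After subtraction of the running median there were 0 regions in all 9 mice, 136 of parents only and 170 sire minus dam. With the mouse in Cy5 only, 493 regions were of parent and offspring, 21 of parents only and 359 of offspring only. With the mouse in Cy3 only, these were 544, 144 and 280, with 3 regions in all 9 mice. Single probes numbered 9495 at 0.5 and 34 at 1.5. Of settings chosen after seeing the data, asking the interval median as well as the mean to pass gave 538 calls, 137 regions of parent and offspring, 121 of parents only, 185 of offspring only, 656 offspring minus mid-parent and 131 sire minus dam. Removing the dye effect of each probe gave 489 regions of parent and offspring. The limma count ranged from 0 to 732 when 1 mouse was left out, at 0 without any 1 offspring, 32 without the sire and 732 without the dam, and was 0 under each other setting, means of 10 neighbouring probes (chosen after seeing the data) among them. The gene-level comparison, the gene lists and their alternatives were not run. No paired test was run, because all offspring have the same 2 parents and so form no separate pairs with them. The median signal was 4.89 to 10.22 times background. Leaving out dim probes gave 1232 calls of all lengths in place of 1537, and the noise tracks with the dye effect removed gave 769 in place of 1340.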

Other observations

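The tests in this part were chosen after the results were seen. Some short autosomal regions divided the family in the same way as the X probes did. On chromosome 3 (25417435 to 25432738, 3 probes) the dam and offspring 3 to 7 lay between -1.67 and -1.49, the sire at 0.13, offspring 1 at -0.01 and offspring 2 at 0.01. On chromosome 9 (35857910 to 35865189, 3 probes) the dam lay at -0.58 and the sire at 0.11, and on chromosome 11 (112961382 to 112965298, 3 probes) at -0.69 and -0.24. On chromosome 5 (109220847 to 109223996, 3 probes) the dam lay at -0.43 and the sire at 0.06. The same mice were high in the chromosome 8 region of 44 probes, at 0.20 to 0.25.

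Sequence shared with the X or Y chromosome, autosomal variants of 1 parent and scan day were weighed. Sire and dam differed by 0.3 or more in 350 regions, 316 of them under 5 probes. In 10 of the 350 all 7 offspring fell with the same parent as on the X probes, and in 0 did all 7 fall with the other parent, where independent Mendelian transmission would give 2.73 each. Among the 20 regions with the highest scores the counts were 4 and 0.156 expected. Other divisions of the offspring passed the same expectation: offspring 2 and 7 alone fell with the dam in 55 of the 350 and in 6 of the 20. All 7 were nearer the dam in 97 of the 350 and all 7 nearer the sire in 26, each in 0 of the 20. Independent Mendelian transmission thus does not describe the 350 regions. The excess along the X probes therefore decides neither for shared sequence nor against autosomal variants, and both stay open.

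Scan day alone is argued against at the chromosome 3 region, since sire and dam, scanned on the same day, differed there by 1.78 in log2, with a score of 20.13 against 11.07 for the highest noise interval under 5 probes in sire minus dam. In the other 9 of the 10 regions the difference of the parents scored below that, and scan day stays open there: offspring 1 and 2 shared 1 scan day and offspring 3 to 7 were scanned on others, the same division as on the X probes. In 83 regions chosen on the offspring alone, as parting these 2 from the other 5, sire and dam differed by 0.3 or more the same way in 10, the opposite way in 5 and by less in 68. The X or Y sequence itself was not searched.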
